A study of Homo sapiens with 4 samples.

How the data were processed

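Each of the 4 microarrays held total RNA of MCF7 cells with an inserted MYF6 gene (line Rec2) and of control cells, labelled with Cy5 and Cy3, and the labels give the dye of each RNA. The labels call the 4 arrays biological replicates. The scanner files give intensity values per spot, that is, median pixel brightness of the spot and of its local background in each dye, read with Agilent Feature Extraction 12.0.3.1 per the file headers. The submitters' processing notes name Agilent Feature Extraction 10.7.3.1, R 3.0.1 and limma, and which version made the values is not settled. Processed intensity values were background-subtracted, spatially detrended and dye-normalized within the array, per the file headers. The deposited log10 ratio column was close to the log10 of red over green processed intensity, with a largest difference of 0.157 on replicate 1, and was used for nothing else.

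The deposited value table of the series holds log2 values whose scale and direction the labels do not state, and they were found by comparison with the scanner intensities. Each column equalled, within 1e-04, the log2 of a ratio of the log2 raw median intensities of 1 dye on 2 arrays, without background correction or normalization. Columns 1 and 2 held green on array 1 over array 3 and on array 2 over array 4, which by the labels is control over Rec2; columns 3 and 4 held red on the same pairs, which is Rec2 over control. The column medians were -0.01, 0.02, -0.08 and 0.02. Of 34085 probes with 1 spot, 23961 (70.3%) were equal in all 4 columns, and 9156 of the other 10124 held the 4 values of another probe within 2e-04. Scale, centring (none) and direction are thereby known for the equal probes and are the same for these 9156, whose values stood under another probe's name; for the rest all of these stay unknown. Only the equal probes were used, as an alternative, and their scale is not that of a log2 fold change. Per-sample columns without a sample numbered 0.

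The main values were computed with limma 3.58.1 in R 4.3.3. The plan named mean spot signals; median signals were used in their place, since the spot tables used here hold no mean columns. Background was corrected with normexp (offset 50) on the median signals and local median backgrounds, followed by loess within each array. Control spots had weight 0 in loess and left the test, and spots marked as non-uniform or population outliers (584 to 695 per array) were left out. No array had a saturated spot among 58717 spots that were not controls (0 in each). Spots of a probe were averaged, a probe entered if well above background on at least 3 of 4 arrays in 1 of the RNAs, and a gene was represented by its probe with the highest mean intensity. Of 42405 probes 21343 passed, and probes of 44 genes passed the test in opposite directions. Accessions were named through a RefSeq table of assembly GRCh38.p14, which gave a symbol to 27241 probes and to 12708 of the 17215 genes tested. The array design was annotated on hg19, so the table served only for names and gene order, and no positions are printed.

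The model held a gene-specific dye intercept and the MYF6 effect, coded 1 where Rec2 RNA carried Cy5 and -1 where it carried Cy3. It was fitted with lmFit and eBayes (2 residual and 6.32 prior degrees of freedom), two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. The dye effect passed the threshold for 1207 genes. Standard errors (SE) are moderated errors of this fit. They leave out what the dye intercept takes up, including any difference between the 2 dye orientations. All arrays lay on 1 slide and were scanned in 1 run, so no slide or scan term could be fitted. A gene not well above background on any array in 1 RNA was given as a bound, "at least N-fold". The bound set the bright side's mean against the dim side's mean of the higher of its own signal and the lowest signal well above background, per channel after loess and Aquantile. It leaves out sampling error, and where the dim signal lay above that lowest signal it equals the fitted fold and is given as such.

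Before the data were examined, 32 gene lists, the tests, the alternatives and the rule for named genes were fixed. The lists were those named in the results. The rule took MYF6, the 10 largest rises and 10 largest falls past the threshold with the same sign on all 4 arrays and an ordinary symbol, and up to 4 members with the smallest p of each described list. A list was described if it passed camera, had at least 3 members past the threshold, or was one of 8 named in advance. Of the lists, 30 had at least 5 tested members and were tested with limma's camera (preset correlation 0.01), with Benjamini-Hochberg adjustment over the 30. Estimated correlation and fry were alternatives; fry tests whether a list's genes move on balance one way, without comparing them with other genes.

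On simulated ratios for 17207 genes with the real spread and dye effects, the fit called 29 of 67 genes moved by 0.5 on the log2 scale, 57 of 67 moved by 1 and 65 of 66 moved by 2. It called 0 genes when none was changed, and 0 of 30 lists. Simulated genes varied independently, so this does not test the list calls where genes are correlated, and no list passed camera with an estimated correlation. Alternatives on background, signal columns, scaling, probe filter, dye term, probe rule, deposited table and left-out replicates were tried. Numbers in parentheses after list counts are camera adjusted p.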

Results

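RNA from human breast cancer cells carrying an introduced MYF6 gene was compared with RNA from control cells on 4 microarrays of 62976 spots each. MCF7 is an estrogen receptor-positive breast cancer line of luminal epithelial character. MYF6 encodes a myogenic regulatory factor, a basic helix-loop-helix transcription factor that drives skeletal muscle differentiation. The MYF6 cells, a line called Rec2, carried the gene at a fixed insertion site, and the cells were treated with doxycycline at 50 ng per ml for 48 h to induce expression, per the labels. Every array held Rec2 RNA in one dye and RNA from control cells in the other, giving 4 replicates of 1 comparison, which the labels call biological. Rec2 RNA carried Cy5 on replicates 1 and 2 and Cy3 on replicates 3 and 4. Between 45.4% and 55.8% of probes were well above background per array and RNA, and 17215 genes were tested. Because arrays give no read depth, precision was limited by their number.

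The comparison asked how the introduced MYF6 gene altered gene expression in these cells. The single MYF6 probe was not well above background in either RNA on any of the 4 arrays. In the Rec2 channel its signals were 71.5, 72.0, 23.0 and 23.0 on replicates 1 to 4, beside local backgrounds of 70.5, 71.0, 25.0 and 24.0. The log2 ratio of these background-level signals was -0.05 ± 0.05 (SE, n = 4 arrays; limma, adjusted p = 0.661 over all probes). Whether the probe lies inside the introduced sequence is not known here, so this probe does not check the labels, and these arrays do not show whether MYF6 was expressed.

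The genes with the largest rises in Rec2 cells included DUSP13A, a dual-specificity phosphatase (log2 change 2.48 ± 0.09 SE, a 5.60-fold rise, n = 4 arrays, limma adjusted p = 7.19e-06). SERPINA3, a secreted protease inhibitor, rose by 2.14 ± 0.15, and TIMP2, an inhibitor of matrix metalloproteinases, by 1.99 ± 0.10. Also among the 10 largest rises were MALRD1 at 2.20, MAGED4B at 2.03, the trefoil peptide TFF3 at 1.86, DCDC2 at 1.86, the lipid carrier APOE at 1.84 and the sialomucin PODXL at 1.76. The progesterone receptor gene PGR was well above background on all 4 arrays in Rec2 RNA and on 0 of 4 in control RNA. Set against the lowest signal well above background, its level was at least 3.16-fold higher in Rec2 cells (limma adjusted p = 0.000223). This bound leaves out sampling error, and the 95% interval of the fitted log2 change was 1.44 to 2.20.

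The largest falls were in BAMBI, a decoy receptor of the TGF-beta family (log2 change -2.63 ± 0.11 SE, a 6.19-fold fall, n = 4 arrays, limma adjusted p = 9.6e-06), and in the calcium-binding protein gene S100P (-2.58 ± 0.10). ALCAM, a cell adhesion molecule, fell by 2.53, with 2 of 4 arrays well above background in Rec2 RNA. LXN, a carboxypeptidase inhibitor, fell by 2.30 and DHRS3, a retinal reductase, by 2.26. CCN5 fell by 2.23, the hypoxia-inducible factor gene EPAS1 by 2.05, and the stem cell transcription factor gene SOX2 by 1.98. HOXB6 fell by 2.03 and RFTN1 by 1.99, each with 3 of 4 arrays well above background in Rec2 RNA. These 20 genes, 10 in each direction, were taken from genes with the same sign on all 4 arrays. BAMBI, and MALRD1 which rose, lie in a run of 50 tested genes on chromosome 10 of which 3 rose and 32 fell. TIMP2 lies in a run of 50 tested genes on chromosome 17 of which 29 rose and 3 fell. The mean log2 changes of these runs were -0.33 and 0.34.

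**Figure D1:**
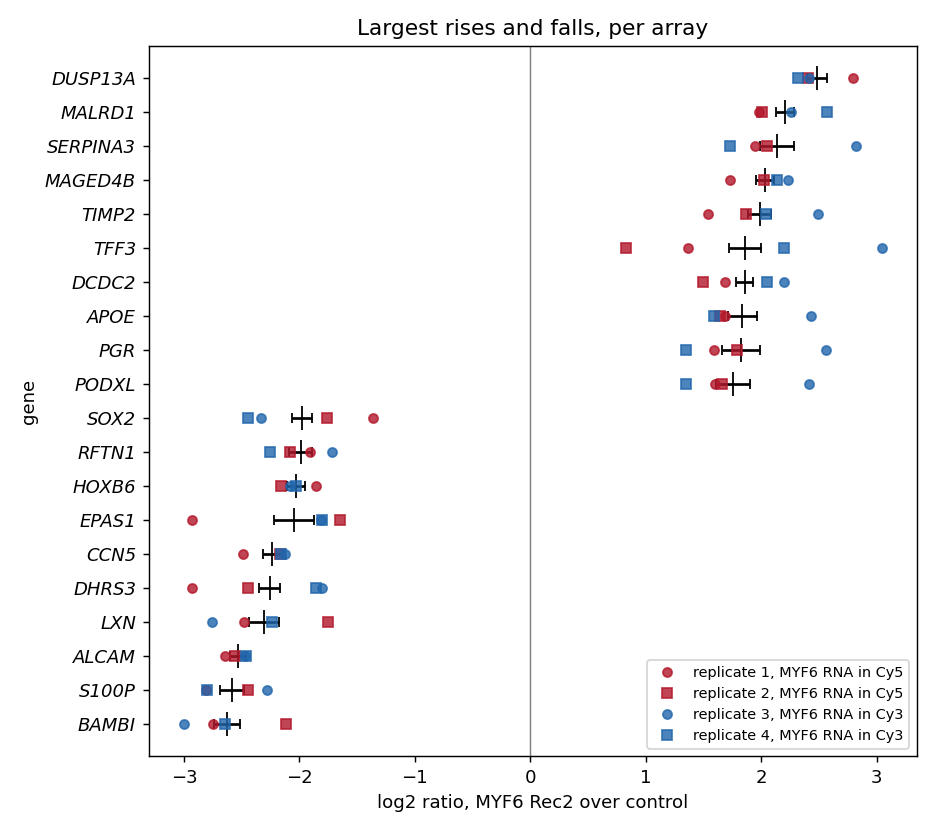
Log2 ratio of Rec2 over control RNA (x axis) for the 10 largest rises and 10 largest falls (y axis). Coloured points are the 4 arrays by dye orientation and black marks the fitted values with their standard errors, from -2.63 for BAMBI to 2.48 for DUSP13A. All points of a gene lie on one side of 0, as the rule for naming them required. PGR was not well above background on any array in control RNA.

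Of the 17215 genes tested, 5751 passed limma's adjusted p of 0.05, 3211 of them higher and 2540 lower in Rec2 cells. The median absolute log2 change of the genes that passed was 0.38, and 202 genes changed at least 2-fold, 127 upward and 75 downward. This count depended on the signals and the offset, since 558 genes changed at least 2-fold with the processed signals and 285 with an offset of 16 in place of 50. On all 4 arrays, 4795 of the changed genes (83.4%) had the same sign. Without a gene-specific dye term the count was 2719, with 1520 higher and 1199 lower. Rises made up 55.8% of calls, against 40.1% when arrays were centred on their median without loess. Turned to one direction, ratios correlated across genes at 0.79 and 0.74 between arrays of the same dye orientation and at 0.38 to 0.48 between orientations; genes are not independent replicates. The dye orientation also separates replicates 1 and 2 from 3 and 4, so a difference between these cultures cannot be told apart from the dye, and 1 MYF6 line was compared. The labels do not say whether arrays 1 and 3, and arrays 2 and 4, held the same RNA with dyes swapped, which would leave 2 independent replicates and not 4. With ratios turned to one direction, the difference between arrays 1 and 2 correlated across genes at -0.19 with that between arrays 3 and 4. Shared RNA in these pairs would push this value above 0, so it does not speak for such sharing. For arrays 1 with 4 and 2 with 3 the same value counts with its sign turned, and so lies above 0. Shared RNA in those pairs would give such a sign and would also leave 2 independent replicates, so it stays open. Pairs within a dye orientation were not examined. With arrays 1 and 3, and arrays 2 and 4, averaged 7065 genes passed (limma). Opposed differences cancel in these averages, so the count is no check on the number of independent replicates.

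Of 44 tested genes that estrogen induces in breast cancer cells 24 rose, 8 fell and 12 did not pass, and adjusted over the list alone 25 rose and 10 fell. The list's median log2 change was 0.36 with an adjusted p of 0.0037 by limma's camera, and the adjusted p was 0.809 with an estimated correlation. TFF3 rose by 1.86 ± 0.14 (SE, n = 4), PKIB, a protein kinase A inhibitor, by 1.37 ± 0.09 and RERG, a small GTPase, by 1.06 ± 0.08. By array TFF3 stood at 1.36, 0.83, 3.04 and 2.20 on replicates 1 to 4, a wider spread than its SE conveys. The keratin gene KRT13 rose by 1.48 ± 0.10, with 3 of 4 arrays well above background in control RNA. KRT13 lies in a run of 50 tested genes on chromosome 17 of which 29 rose and 0 fell. GREB1, an estrogen receptor cofactor, rose by 0.88, whereas SLC7A5, an amino acid transporter, fell by 0.65; these 2 members were chosen after their values were seen.

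**Figure D2:**
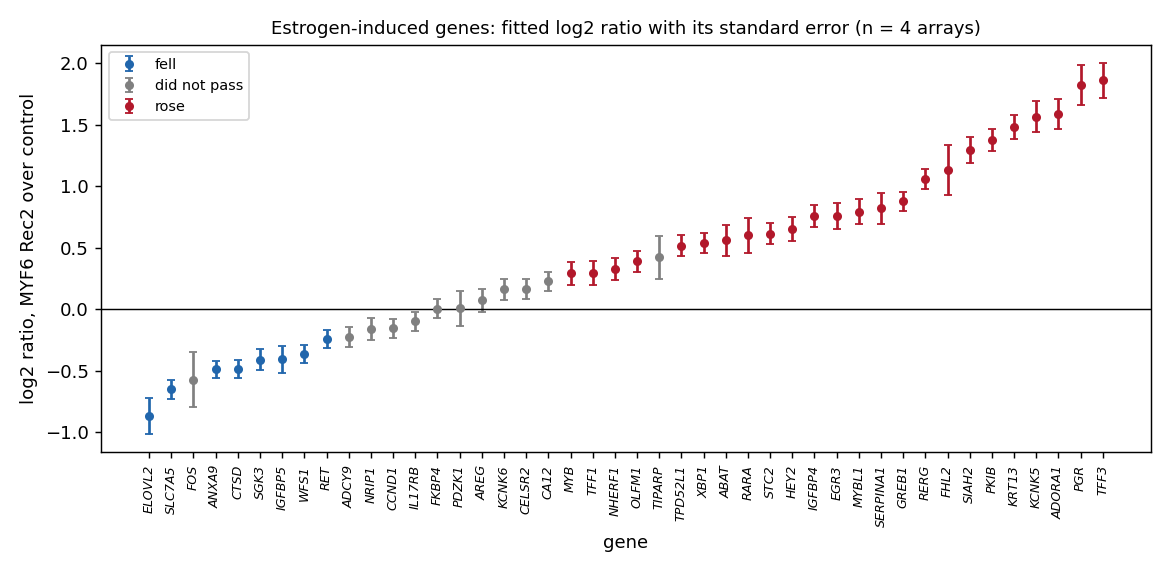
Fitted log2 ratio of Rec2 over control RNA (y axis) with its standard error for each of the 44 tested estrogen-induced genes (x axis, ordered by value; n = 4 arrays). The 24 genes that rose are red, the 8 that fell blue and the remaining 12 grey. TFF3 lies highest at 1.86, and PGR was not well above background on any array in control RNA.

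Skeletal muscle genes were detected in small number, and most of those that changed rose. Of 61 listed structural and excitation genes 17 were tested, of which 11 rose, 2 fell and 4 did not pass; adjusted over the list alone the counts were also 11 and 2. TPM1, which encodes a tropomyosin found in muscle and other cells, rose by 0.86 ± 0.08 (SE, n = 4), and SGCB, a sarcoglycan, by 0.76 ± 0.07. CDH15, the cadherin of muscle cells, rose 2.30-fold, with 2 of 4 arrays well above background in control RNA, while the junctophilin gene JPH2 fell by 1.05 ± 0.07. The median was 0.31 with an adjusted p of 0.00626 by limma's camera, and the adjusted p was 0.809 with an estimated correlation. With all probes entered, detected or not, the median was 0.0083 and the camera adjusted p 0.168; the strict filter gave 0.29 and 0.0523, and the processed signals moved the median to 0.54.

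Of 13 listed myogenic regulatory factors other than MYF6, 6 were tested, of which 2 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.851). SIX4, a homeobox transcription factor, rose by 0.57 ± 0.08 and its paralog SIX1 fell by 0.47 ± 0.09. MEF2A rose by 0.33 ± 0.10 and EYA2 fell by 0.29 ± 0.08, but without the dye term their limma adjusted p was 0.115 and 0.081. Among basic helix-loop-helix partners and inhibitors, 9 of 13 tested rose and 2 fell, also when adjusted over the list alone (median 0.39, camera adjusted p = 0.0362). Its adjusted p was 0.809 with an estimated correlation. ID2, an inhibitor of these factors, rose by 0.56 ± 0.08, HEY2 by 0.66 ± 0.10 and TCF3, a dimerisation partner of myogenic factors, by 0.39 ± 0.07, the last without passing when arrays were centred on their median. BHLHE40 rose by 0.52 ± 0.07, a call that ended without the dye term (adjusted p = 0.129, limma). Without the filter on dim probes the list's median was 0.065 (camera adjusted p = 0.0553), and without replicate 3 it was 0.23 (0.0949). The camera adjusted p was 0.0717 with median centring and 0.0523 with the strict filter.

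Of 45 tested replication-dependent histone genes 24 rose, 0 fell and 21 did not pass, and 31 rose when adjusted over the list alone. H3C3 rose by 0.51 ± 0.10 (SE, n = 4), H2BC5 by 0.45 ± 0.10, H3C4 by 0.43 ± 0.10 and H3C8 by 0.41 ± 0.09, the last pair without passing when arrays were centred on their median. The median was 0.30 with a camera adjusted p of 2.57e-05, and the adjusted p was 0.812 with an estimated correlation. By array the median was 0.22, 0.34, 0.56 and 0.02 on replicates 1 to 4; without replicate 3 the list's median was 0.18 and with median centring 0.16. The 11 tested genes that lie among these histone genes on chromosome 6 without being histones had a median of 0.26. Histone genes are near-identical copies, so a probe can report more than 1 of them. The histone gene H4C1 had probes that passed in opposite directions, so the counts rest on the probe chosen for each gene.

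Of 46 tested genes of G1/S and DNA replication 2 rose and 8 fell, with equal counts adjusted over the list alone (median -0.10, camera adjusted p = 0.04, and adjusted p = 0.841 with an estimated correlation). MCM5, a subunit of the replicative helicase, fell by 0.64 ± 0.10 and the transcription factor gene E2F1 by 0.45 ± 0.08. BRCA1 rose by 0.40 ± 0.08 and UHRF1 fell by 0.28 ± 0.07, with adjusted p of 0.173 and 0.245 in limma without the dye term. Of 47 genes of G2/M and mitosis 3 rose and 7 fell, also adjusted over the list alone (median -0.13, camera adjusted p = 0.0347, and adjusted p = 0.841 with an estimated correlation). The proliferation marker MKI67 fell by 0.50 ± 0.08 and the mitotic kinase gene CDK1 by 0.41 ± 0.09. CCNA2 fell by 0.59 ± 0.12 and TOP2A rose by 0.47 ± 0.10; without the dye term limma gave them adjusted p of 0.0792 and 0.167. The medians of both lists turned with the dye orientation, at 0.14, 0.11, -0.46 and -0.13 on replicates 1 to 4 for G1/S and at 0.11, 0.11, -0.54 and -0.09 for G2/M. Without replicate 3 their medians were -0.02 each, with camera adjusted p of 0.509 for G1/S and 0.721 for G2/M, whereas without replicate 4 they were -0.18 (0.000882) and -0.23 (4.86e-05). For G1/S camera also gave an adjusted p of 0.0925 without replicate 2, 0.0606 without the dye term and 0.0523 with the strict filter, and the processed signals gave 0.06 for both.

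Genes of hypoxia and glycolysis rose in 16 of 32 tested cases and fell in 2 (17 and 2 adjusted over the list alone). The median was 0.22, the camera adjusted p was 0.0037, and the adjusted p was 0.809 with an estimated correlation. This direction also turned with the dye orientation, since the list's median was -0.11 and -0.31 on replicates 1 and 2 and 0.67 and 0.60 on replicates 3 and 4. P4HA2, a collagen prolyl hydroxylase, rose by 1.12 ± 0.07, BNIP3L, a mitophagy receptor, by 1.12 ± 0.12, the enolase gene ENO2 by 0.84 ± 0.07 and the glucose transporter gene SLC2A1 by 0.52 ± 0.07. BNIP3L ranged from 0.27 on replicate 1 to 1.84 on replicate 4. Of 30 tested members of the type I interferon response, 12 fell, 1 rose and 17 did not pass, also adjusted over the list alone (median -0.26, camera adjusted p = 0.00626). The adjusted p was 0.841 with an estimated correlation. USP18 fell by 0.49 ± 0.07 and PARP9 by 0.52 ± 0.08, HERC5 fell by 0.53 with 1 of 4 arrays well above background in Rec2 RNA, and STAT2 was the member that rose (0.67 ± 0.11). By array the list's median was -0.28, -0.08, 0.09 and -0.62 on replicates 1 to 4. Without replicate 4 the list's median was -0.05 and its camera adjusted p 0.302, whereas without replicate 3 they were -0.44 and 5.32e-10; the strict filter gave -0.16 and 0.0603.

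Cholesterol biosynthesis genes fell in 10 of 24 tested cases and rose in 1 (11 and 1 adjusted over the list alone; median -0.17, camera adjusted p = 0.00916, and adjusted p = 0.809 with an estimated correlation). DHCR7, a reductase of the last steps of the pathway, fell by 0.83 ± 0.10, STARD4 by 0.65 ± 0.08, IDI1 by 0.54 ± 0.09 and the mevalonate kinase gene MVK by 0.38 ± 0.08. The list's median was -0.11 without replicate 3 (camera adjusted p = 0.0579) and also -0.11 without replicate 1 (0.0205). LSS, a member of this list, had probes that passed in opposite directions. Of 9 tested genes of the ErbB receptor family and its ligands, 5 rose and 0 fell (6 and 0 adjusted over the list alone; median 0.27, camera adjusted p = 0.04, and adjusted p = 0.809 with an estimated correlation). The receptor tyrosine kinase genes ERBB2 and ERBB4 rose by 0.77 ± 0.09 and 0.50 ± 0.10, and the adaptor gene GRB7 by 0.44 ± 0.07. ERRFI1 rose by 0.47 ± 0.14, with an adjusted p of 0.147 without the dye term (limma). With all 17 members entered, detected or not, the list's median was 0.033 (camera adjusted p = 0.0636). Camera gave adjusted p of 0.068 with the processed signals, 0.0516 with median centring, 0.0564 without the dye term and 0.152 without replicate 3. ERBB2 and GRB7 are near neighbours on chromosome 17, inside a run of 50 tested genes of which 29 rose and 0 fell.

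**Figure D3:**
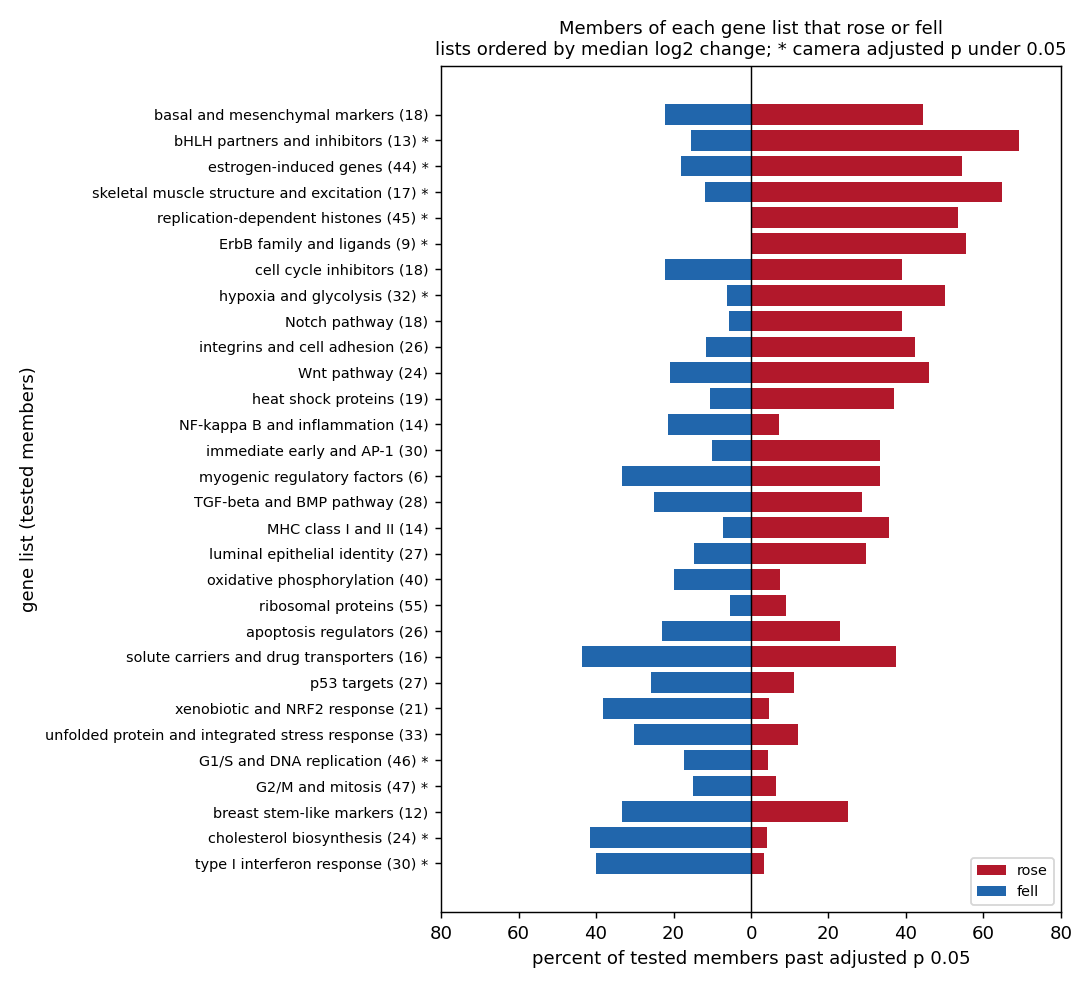
Percent of tested members of each gene list that rose (red, to the right) or fell (blue, to the left) in Rec2 cells at an adjusted p under 0.05. The number of tested members stands in parentheses, lists are ordered by their median log2 change, and an asterisk marks the 10 lists past the camera test; of the 45 histone genes 24 rose and 0 fell.

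Centring arrays on their median in place of loess moved further medians by over 1.5 times, to 0.23 for estrogen-induced genes, 0.088 for hypoxia and glycolysis, -0.19 for G1/S, -0.27 for G2/M, -0.28 for cholesterol biosynthesis and 0.17 for the ErbB list.

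The remaining 20 lists tested did not pass camera. In the luminal list 8 of 27 rose and 4 fell (camera adjusted p = 0.526). The estrogen receptor gene ESR1 rose by 0.64 ± 0.07 (SE, n = 4) and the keratin gene KRT19 by 0.98 ± 0.07, whereas the androgen receptor gene AR fell by 0.99 ± 0.14 and AGR2 by 1.11 ± 0.09. In the deposited table ESR1 lay below 0, as given under processing. KRT19 lies in a chromosome 17 run of 50 tested genes that mostly rose, and AGR2 in a chromosome 7 run that mostly fell. Among basal and mesenchymal markers 8 of 18 rose and 4 fell (0.164), with the collagen gene COL5A1 up 2.30-fold, COL6A1 up by 0.56 ± 0.07 on the log2 scale, the integrin gene ITGB4 up by 0.59 ± 0.07 and TGFBI down by 1.64 ± 0.13. For both lists the counts were the same adjusted over the list alone. The basal list passed camera without replicate 1 (median 0.45, adjusted p = 0.0399) and without replicate 4 (0.48, 0.0299), but not without replicate 2 or 3. Its median was 0.45 with all arrays, and by array 0.04, 0.26, 0.35 and 0.08 on replicates 1 to 4. Of 4 tested markers of fibroblasts and blood cells, COL1A1 rose by 0.50 ± 0.08; the others had log2 changes of 0.25 for APOA1, -0.11 for VWF and -0.01 for PTPRC, and adjusted over the list alone 2 rose. Neuronal genes had 4 tested members, of which 1 fell and 0 rose, with the same counts adjusted over the list alone.

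Genes of the xenobiotic and NRF2 response fell in 8 of 21 cases and rose in 1 (camera adjusted p = 0.0742). The cystine transporter gene SLC7A11 fell by 1.82 ± 0.08 and the cytochrome P450 gene CYP1B1 by 1.82 ± 0.10, while UGT1A6 rose by 0.94 ± 0.10; HMOX1 fell by 0.53 ± 0.08, with an adjusted p of 0.0903 without the dye term (limma). Adjusted over the list alone 9 fell and 1 rose. From a median of -0.063, this list passed camera with median centring (-0.26, adjusted p = 0.00258), without the filter on dim probes (-0.13, 0.014) and without replicate 1 (-0.12, 0.0205) or replicate 2 (-0.083, 0.0237). Among 33 genes of the unfolded protein and integrated stress response 4 rose and 10 fell (0.172), including ATF5 at -0.65, PSAT1 at -0.56 and DNAJC3 at -0.53; adjusted over the list alone 7 rose and 11 fell, and with median centring the list passed camera (median -0.15, adjusted p = 0.0148). Solute carriers and drug transporters went both ways, with 6 of 16 up and 7 down (0.711). SLC1A1 rose by 1.42 with 2 of 4 arrays well above background in control RNA, and the zinc transporter gene SLC39A6 rose by 1.43. ABCA1, not well above background on any array in Rec2 RNA, was 1.81-fold lower there in the fit (limma adjusted p = 0.000154). For ABCA1 the bound equals this fitted fold, and the 95% interval of its log2 change was -1.02 to -0.70. Among 19 heat shock protein genes 7 rose and 2 fell (0.091). HSPA1A rose by 0.88 and HSPB8 by 0.64; HSPA1B and HSPH1 rose by 0.65 and 0.54 but had adjusted p of 0.0759 and 0.123 without the dye term (limma). The heat shock list passed camera without the filter (median 0.080, adjusted p = 0.033) and without replicate 3 (0.20, 0.0238). Its median was 0.13 with all arrays, but 0.39, 0.34, -0.31 and 0.03 on replicates 1 to 4, so the rise was not held in both dye orientations. Among 14 MHC genes 5 rose and 1 fell (0.107), and the related HLA-DRB1, HLA-G, HLA-C and HLA-F rose by 0.98, 0.73, 0.71 and 0.69, although their probes can share targets. The MHC list passed camera without replicate 1, 2 or 4, with medians of 0.10, 0.039 and 0.15 and adjusted p of 0.0294, 0.0342 and 0.0359. By array its median was -0.10, 0.02, 0.34 and 0.21 on replicates 1 to 4, so it differed with the dye orientation. HLA-F stood at 0.24, 0.22, 1.35 and 0.96 on the same arrays.

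Wnt pathway genes rose in 11 of 24 cases and fell in 5 (camera adjusted p = 0.278). The transcription factor gene LEF1 rose by 1.35 ± 0.10 and the receptor gene FZD4 by 0.64 ± 0.08, and the Wnt inhibitor gene DKK1 fell by 1.52 ± 0.13. SP5, not well above background on any array in control RNA, was at least 1.49-fold higher in Rec2 cells (limma adjusted p = 0.000361). Notch pathway genes rose in 7 of 18 cases and fell in 1 (0.079), with LFNG at 0.80, RFNG at 0.37 and RBPJ at 0.35, the last without passing when arrays were centred on their median. Without the filter on dim probes the Notch list passed camera (median 0.063, adjusted p = 0.0158). Of 28 genes of TGF-beta and BMP signalling 8 rose and 7 fell (0.851), with SMAD4 at 0.64, INHBB at 0.54 and SMAD3 at -0.67 beside BAMBI. Integrin and adhesion genes rose in 11 of 26 cases and fell in 3 (0.091), with CDH18 at 0.74; LAMB2 rose by 0.51, with an adjusted p of 0.0716 without the dye term (limma). This list passed camera without the filter (median 0.059, adjusted p = 0.0436) and with the strict filter (0.21, 0.0199). Among 30 immediate early genes 10 rose and 3 fell (0.264), and the list passed camera without replicate 2 (median 0.21, adjusted p = 0.00382) and without replicate 4 (0.30, 0.00117). With all arrays the median was 0.12, and by array it was 0.11, -0.17, 0.70 and 0.21 on replicates 1 to 4, highest on replicate 3. EGR3 rose by 0.76; FOSL2 rose by 0.61 with 2 of 4 arrays above background in control RNA, and FOSL1 and SPRY2 fell by 0.51 each, with 3 and 1 of 4 arrays above background in Rec2 RNA.

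Breast stem-like markers rose in 3 of 12 cases and fell in 4 (camera adjusted p = 0.264), with ALDH1A3 at -1.43, the chemokine receptor gene CXCR4 at -0.63 and ITGA6 at 0.51 beside SOX2. The stem-like list passed camera with median centring (median -0.22, adjusted p = 0.0113) and without replicate 2 (-0.15, 0.00961). Of 18 cell cycle inhibitor genes 7 rose and 4 fell (0.612), including GADD45G at 0.80, CCNG2 at 0.53, CDKN2C at -0.66 and CDKN2A at -0.42. Among 27 p53 targets 3 rose and 7 fell (0.444). The death receptor gene FAS fell by 0.60 and POLK rose by 0.74; DDB2 fell by 0.33 and TP53INP1 rose by 0.35, with adjusted p of 0.0867 and 0.0539 without the dye term (limma). Apoptosis regulators rose in 6 of 26 cases and fell in 6 (0.993). BCL2, which blocks apoptosis, rose by 1.09 ± 0.07, TNFRSF10A fell by 0.45 and HRK by 0.51, and MCL1 rose by 0.42 with an adjusted p of 0.12 without the dye term (limma). Inflammation genes of the NF-kappa B list rose in 1 of 14 cases and fell in 3 (0.993), with a median of 0.39 and a camera adjusted p of 0.0417 without replicate 4. SOD2 fell by 0.82, and CCL5 by 0.73 with 1 of 4 arrays well above background in Rec2 RNA. IL6, not well above background on any array in Rec2 RNA, was at least 1.5-fold lower there (limma adjusted p = 0.00139). By array CCL5 stood at -0.63, -0.40, -0.39 and -1.50 on replicates 1 to 4. LIF rose by 0.64, with an adjusted p of 0.0626 without the dye term (limma).

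Oxidative phosphorylation genes rose in 3 of 40 cases and fell in 8 (camera adjusted p = 0.592), with COX6C at 0.74 and NDUFS3 at -0.37; PPARGC1B fell by 0.41 and NDUFB5 rose by 0.44, with adjusted p of 0.0855 and 0.121 without the dye term (limma). Of 55 ribosomal protein genes 5 rose and 3 fell (0.851), among them RPL27 at 0.55, RPL19 at 0.52, RPS25 at -0.66 and RPS24 at -0.57. Adjusted over the list alone, rises and falls numbered 12 and 3 for integrins and adhesion, 10 and 4 for immediate early genes, 9 and 7 for TGF-beta and BMP, and 2 and 7 for oxidative phosphorylation. They numbered 8 and 5 for cell cycle inhibitors, 5 and 2 for ribosomal proteins and 7 and 8 for apoptosis regulators. For transporters, heat shock, MHC, Wnt, Notch, stem-like, p53 and NF-kappa B genes they equalled those over all genes. The median and the mean of a list differed in sign for TGF-beta and BMP, oxidative phosphorylation, apoptosis and the neuronal genes. The camera direction opposed the median for oxidative phosphorylation, ribosomal proteins and apoptosis, and the direction of limma's fry opposed it for NF-kappa B as well. Centring arrays on their median in place of loess turned the medians of the TGF-beta and BMP, heat shock, luminal, myogenic, oxidative phosphorylation and ribosomal lists below 0.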

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

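No explanation was tested for the values in this part, and the look at the spike-in probes was chosen after the data were seen. In 9 of 168 results checked, 1 array stood apart from the other 3, measured as its gap to the nearest array over the whole range; chance alone gives about 1 in 20, or 8.4. The lipid carrier gene APOE had a log2 ratio of 2.43 on replicate 3 and 1.59 to 1.68 on the others (gap over range 0.886). EPAS1 stood at -2.93 on replicate 1 against -1.81 to -1.65 (0.873), and CCN5 at -2.49 on replicate 1 against -2.17 to -2.12 (0.875). IL6 stood at -1.12 on replicate 1 against -0.57 to -0.55 (0.96), with Rec2 signals not well above background on any array. The small heat shock protein gene HSPB8 was at 1.09 on replicate 3 and at 0.49 to 0.50 elsewhere (0.973). PSAT1, of serine synthesis, was at -0.81 on replicate 3 and at -0.49 to -0.46 elsewhere (0.927), and the death receptor gene TNFRSF10A at -0.68 on replicate 2 and -0.37 to -0.36 elsewhere (0.989). The median of the NF-kappa B list was 1.07 on replicate 3 and -0.14 to -0.01 on the other arrays (0.891), and that of the unfolded protein and integrated stress response list -0.13 on replicate 3 and -0.04 to -0.02 (0.835).

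Among control spots left out of all comparisons, 10 spike-in probes were well above background at every spot in both dyes. Their median log2 ratio of red over green was 0.55, 0.84, -0.44 and 0.43 on replicates 1 to 4. These ratios come from the processed signals, already background-subtracted and dye-normalized within the array. The lowest correlation of these probes between arrays was 0.998, across probes, which are not independent replicates.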

How the results depend on the processing

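The alternatives that kept the marked spots, centred the deposited table and averaged arrays 1 with 3 and 2 with 4 were chosen after the data were seen. The number of arrays limits the precision. Green medians were 72.5 to 79.5 over backgrounds of 22 to 24; with dim probes entered 34390 genes were tested and 5740 passed, and with the strict filter 15012 and 5268, beside 17215 and 5751. The dye term changed the count of calls and median centring the balance of rises, as given below. No call of the 5751 was reversed under any setting of the scanner values, although 19 changed sign without a call with the mean over a gene's probes. Without the dye term, with arrays averaged in pairs and with the other dim-probe filters, fitted changes stay nearly the same. Those settings could therefore hardly reverse a call. Aquantile leaves ratios unchanged and says nothing about stability, leaving out the marked spots was already the setting used, and the slide or scan alternative was not run because all arrays shared 1 slide and 1 scan. The strict filter and the mean over probes gave no value for MYF6.

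With arrays 1 with 3 and 2 with 4 averaged 7065 genes passed, a count that is no check on the number of independent replicates. Without the dye term 2719 genes passed (1520 higher, 1199 lower); with treat 1119 (650 and 469); and with at least 2-fold 202 (127 and 75). Median centring gave 1866 higher of 4652. The deposited table gave 242 of 10396 genes (111 and 131) and, centred, 1807 (1003 and 804). Leaving out 1 replicate gave 3923 to 6466 genes, the fewest without replicate 2. Of the 133 named genes that passed, 18 lost the call without the dye term, 8 with median centring, 3 with processed signals and 2 without the filter. Calls also ended for UHRF1 without replicate 1 or 2, for EYA2 and MEF2A without replicate 2 or 3, for TP53INP1 without replicate 2 and for ERRFI1 without replicate 3. Of 10 list shifts, 0 passed with an estimated correlation and 0 passed fry; the 1 list past fry, the xenobiotic and NRF2 response, was not among them. In the deposited table, over fewer members, 3 of the 10 passed and 3 did not, and when it was centred 4 passed and 2 did not. The rest of the 10 had fewer than 5 members there and were not tested. With integrins and cell adhesion, not among the 10, the lists that passed numbered 4 and 5 (adjusted p 0.0328 and 0.0074, camera). Leaving out 1 replicate gave 6 to 13 lists, the fewest without replicate 3.

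Median centring turned MYF6 to 0.054 (adjusted p 0.881, limma) and the list medians of TGF-beta and BMP to -0.025, heat shock to -0.035, luminal identity to -0.077, myogenic factors to -0.024, oxidative phosphorylation to -0.16 and ribosomal proteins to -0.18. The last of these passed camera there, at an adjusted p of 0.0214. Without background correction the ribosomal median was -0.00029. With an offset of 16 it was -0.0076 and that of oxidative phosphorylation -0.0020, and with processed signals they were -0.018 and -0.0045. The mean over probes gave 0.052 for apoptosis, -0.024 for myogenic factors and -0.024 for oxidative phosphorylation. On the scale of the deposited table, not a log2 fold, ESR1 was at -0.032, Notch at -0.030, heat shock at -0.024, luminal identity at -0.029, oxidative phosphorylation at -0.016, ribosomal proteins at -0.021 and the xenobiotic and NRF2 response at 0.0097. Centred, ESR1 was at -0.013, Notch at -0.011, heat shock at -0.0053, luminal identity at -0.010, ribosomal proteins at -0.0017 and the xenobiotic list at 0.029. With 1 replicate left out, medians ranged from -0.038 to 0.033 for apoptosis, -0.11 to 0.037 for p53 targets, -0.060 to 0.0039 for transporters, -0.019 to 0.025 for oxidative phosphorylation, -0.022 to 0.031 for ribosomal proteins and -0.037 to 0.39 for NF-kappa B, and PTPRC from -0.033 to 0.0093. None of these lists passed with all arrays and the settings of the results; the causes were not tested.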

Other observations

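The gene groups in this and the next paragraph, and the tests on S phase, on signal processing and across dye orientations, were chosen after the results were seen. Metallothionein genes, whose products bind zinc and copper, fell in 7 of 8 tested cases and rose in 0 (median log2 change -1.34, limma's camera adjusted p = 3.73e-08 over 6 such groups). The adjusted p was 0.289 with an estimated correlation. MT1E fell by 1.54 ± 0.07 (SE, n = 4 arrays), MT1B by 1.63 ± 0.09 and MT1X by 1.19 ± 0.07, and 7 passed without the dye term. These genes are near-identical copies whose probes can share targets. HOX genes, which encode transcription factors of body patterning, fell in 8 of 15 cases and rose in 0 (median -0.38, camera adjusted p = 0.000932, and adjusted p = 0.289 with an estimated correlation). HOXA5 fell by 0.83, HOXC13 by 0.60 and HOXA4 by 0.58, beside HOXB6. Of the genes that fell, HOXA4, HOXA5, HOXA7 and HOXA9 lie in the chromosome 7 run from TMEM106B to PLEKHA8 described below. In that run 34 genes fell and 1 rose, while HOXA3 and HOXA10 did not pass. A change over the stretch cannot be told apart from one of the gene group.

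Keratin genes rose in 7 of 20 cases and fell in 1 (camera adjusted p = 0.114), with KRT15 up by 1.53 and KRT81 by 1.07 and KRT4 down by 1.60. Of those that rose, at least KRT13, KRT15 and KRT19 lie in the chromosome 17 run described below, where 29 genes rose and 0 fell. Whether KRT10, KRT32, KRT81 and KRT83, which also rose, lie in that run is not given here. A change over that stretch cannot be told apart from one of the gene group. KRT8 and KRT18 had log2 changes of 0.01 and -0.03. In retinoid metabolism 4 of 16 rose and 5 fell (0.278), with the retinoic acid hydroxylase gene CYP26A1 up by 1.27, RDH12 down by 1.05 and the retinol uptake gene STRA6 down by 0.96. S100 genes rose in 3 of 14 cases and fell in 6 (0.171), and MAGE genes rose in 2 of 5 and fell in 1 (0.0533).

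Genes far apart in order on a chromosome changed together. Between tested genes 20 to 50 places apart, log2 changes correlated at 0.0855 over 12693 genes, against at most 0.0061 in 1000 shuffled orders, and of 11566 runs of 50 genes 252 had a mean above and 497 a mean below every run of 200 shuffled orders. The run from TMEM106B to PLEKHA8 on chromosome 7 had the lowest mean (-0.44), with 1 gene that rose and 34 that fell, and the run from RPL19 to P3H4 on chromosome 17 the highest (0.41), with 29 and 0. Among the named genes, the chromosome 17 run holds RPL19, ERBB2, GRB7, TOP2A, KRT13 and KRT19, and the chromosome 7 run AGR2 and IL6. Further chromosome 17 runs hold TIMP2 (29 rose, 3 fell), ITGB4 (28 and 1) and CCL5 (30 and 1), although CCL5 itself fell. A chromosome 10 run (3 and 32) holds BAMBI, and MALRD1 which rose. A chromosome 11 run (0 and 34) holds RPS25, and APOA1 which did not pass. Dye effects of tested genes 20 to 50 places apart correlated at 0.0601. The comparison of this value with 0.0855, planned before the results were seen, met neither of its criteria. It could not decide on a dye bias shared by neighbours. A dye bias shared by neighbours turns sign with the orientation, so a correlation of 0.0513 across orientations (at most 0.0030 when shuffled) argues against it as the whole cause. Gain or loss of chromosome segments in one line is a candidate explanation and stays a hypothesis; sequence composition was not tested.

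The rise of histone genes may belong to this pattern. The 11 genes inside the chromosome 6 histone cluster that are not histones had a median of 0.26 (bootstrap over genes, 95% 0.15 to 0.50) beside the histones' 0.30, a level that 3.31% of 12403 equal runs reached. A larger share of cells in S phase cannot be told apart: the G1/S list's median was -0.10, but 0.14, 0.11, -0.46 and -0.13 on replicates 1 to 4. Over 4 alternatives on signal and scaling the histone median was at least 0.16 beside 0.30, which argues against these choices as the whole cause. The alternatives share the same scans, and their fitted changes correlated with the main ones at 0.943 to 0.998. A fault common to all of them was therefore not tested. The camera adjusted p was at most 0.00237 over these, but 0.812 with an estimated correlation. An effect of MYF6 on histone genes themselves was not tested.

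The rise of estrogen-induced genes had a median of at least 0.23 beside 0.36 over the same 4 alternatives. This argues against these choices of signal and scaling as the whole cause, with the same limit as for the histones. The camera adjusted p was at most 0.00721 over these, but 0.809 with an estimated correlation. The rise held in both dye orientations, with medians of 0.42 (0.11 to 0.53) and 0.44 (0.15 to 0.76), against a bias in 1 of them. The intervals in this paragraph are 95% bootstraps over the 44 genes. Genes are not independent replicates, so these intervals do not measure the spread between arrays. After the median of the 20 nearest tested genes was subtracted, the median was 0.24 (-0.01 to 0.55) beside 0.36 (0.12 to 0.61), so changes over chromosome stretches cannot be told apart, since the interval is wide. An effect of MYF6 on estrogen response could remain and was not separated from the line.

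With arrays turned in each of 8 patterns and no dye term, the real pattern gave 2719 genes and the highest other 0, so 1 pattern reached the real count; 8 patterns are too few for a share under 0.05.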
